A study of Homo sapiens with 34 samples.

How the data were processed

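Bulk poly-A RNA was sequenced from MDA-MB-468, a human triple-negative breast cancer cell line, and from subclonal lines named SCP with a number. Per the labels' protocols, each line was plated in culture dishes in DMEM with fetal bovine serum, passaged at least once more in the same way and lysed on the dish. Per the same protocols, libraries were made with the KAPA mRNA HyperPrep kit with poly-A enrichment and sequenced on NextSeq flow cells, paired-end with 50 cycles, in 2 pools. Which library was in which pool is not given in the sources used here, so no value within a pool could be computed. Per the submitters' processing notes, cutadapt 1.8 and the genome build GRCh37 were used. The aligner, the counting tool, the annotation and the use of strand are not given in the sources used here, so the reads of overlapping or antisense genes, and of near-identical copies, are treated as uncertain.

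The authors deposited 1 table of TPM, transcript abundance scaled to a fixed total per library, with 1 column per library, an Ensembl identifier and a gene symbol on each line. Each column of this deposited TPM table summed to 1e+06 over its 15675 lines. Of these lines, 861 repeated the values of 595 identifiers that occur several times, with 0 identifiers whose repeats differed, and each identifier was kept once, which left 14814. TPM holds no depth by itself. With each library scaled by 1 factor, however, the values of a gene across the libraries were whole multiples of a common step. Whole reads could thus be recovered for 14800 genes, or 99.9%, within a tolerance of 2e-08 of the value plus 1e-06 of a read. The 14 other genes were left out of values that need reads. The recovered reads summed to between 8.64e+06 in SCP24, the shallowest library, and 6.49e+07 in SCP13, the deepest, with a median of 3.03e+07. They were used for depth, for the comparison of library pairs and for 1 alternative test, and never for the results given first. No column of other samples was used.

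Symbols were taken from the file; 1105 genes had none and are not named. A gene name table matched 14479 identifiers, and GENCODE 29, an annotation of GRCh38, gave a biotype for 14520. Neighbour order and chromosome names came from a RefSeq table of GRCh38.p14, which placed 11807 of the tested genes; because its build differs from that of the files, no coordinate is given. GC content was the median over the GENCODE 29 transcripts of a gene and was had for 13498 tested genes, or 98.1%.

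The tests were run in limma 3.58.1 under R 4.3.3 on log2(TPM + 1), so every fold is on that scale, which understates changes of low genes. Genes with a mean of at least 1 TPM over the 34 libraries, 13762 in all, were tested, and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The model had 1 coefficient for each of the 32 lines and a mean-variance trend. Only SCP32 and the parental line have repeat libraries, 2 each, so 2 residual degrees of freedom carry the spread, to which the model added a median of 4.43 prior degrees of freedom; lines with a single library were assumed to vary like those. A moderated F test asked which genes varied among the 31 subclones, and a moderated test compared SCP32 with the parental line. A further test set 1 line against the 31 others, with 1 value per line. The labels do not say whether repeat libraries came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

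A set of 40 gene lists was fixed before the data were examined, as were the tests, most of the alternatives and the rule for naming genes. The 34 lists with at least 5 tested members were compared between SCP32 and the parental line with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Lists were also scored for coherence, as the mean pairwise Pearson r of their members over the 31 subclones against 10000 random lists of equal size matched on mean level, one-sided. A list score is the mean z value of its members over the subclones, and 19 relations between scores were tested with 100000 permutations, two-sided; a relation with AREG was not analysed here. Genes at 10 TPM or more in at least 1 line and under 0.5 TPM in at least 1 other were counted without a test. The named genes are, for SCP32 against parental, the 10 largest rises and 10 largest falls past the threshold with non-overlapping libraries; among the subclones, up to 20 genes past the F threshold by SD; of the on and off genes, the 10 with the highest TPM; of single lines, the 3 largest rises and falls; and of each list, up to 4 members with the largest SD or difference. The members of the line identity list and the genes of the fixed relations are named as well, and features that are pseudogenes or lack a symbol are passed over. A few of these genes, and 1 of the tested lists, are not reported here.

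Alternatives were another pseudocount (0.1), no filter, a filter at a mean of 5 TPM, quantile normalization, each repeat library left out in turn, another variance prior, the replicate number as a block and other thresholds. Chosen after the data were seen were leaving out SCP14 or SCP24, limma-voom on the recovered reads, TPM rescaled over unique identifiers, and corrections for gene length, GC content or both, each of which subtracted from every library its median deviation in 50 bins of genes. Runs of neighbouring genes were also examined only afterwards, with windows of 50 genes in the GRCh38 order and 1000 shuffles.

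The tests were tried on simulated data with 13762 genes. The simulated noise was independent between genes and libraries, without trends with GC content, gene length or replicate number, so the rates need not hold in these libraries. For the F test the change was given to many subclones at once, and a change in a single subclone was not simulated. The F test called 98 of 100 genes given a log2 change of 2, 2 of 100 given a change of 1, and 17 of 13562 left unchanged. The test of SCP32 against parental called 96 of 100 genes at a log2 change of 2, 14 of 100 at 1, and 12 of 13562 unchanged. The test of 1 line against 31 called 92 of 100 at 2, 99 of 100 at 4, and 11 of 13562 unchanged. The coherence test called 20 of 20 lists given a shared factor with an SD of 0.15 and 1 of 20 without one. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.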

Results

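To describe transcriptional heterogeneity among subclonal populations of MDA-MB-468, 34 libraries were compared. The labels give 31 subclones, of which 30 have 1 library and SCP32 has 2, and the parental line with 2, so 32 lines in all; the series' own design text counts 22 subclones. Whole reads recovered from the TPM values gave a depth of 8.64e+06 reads (SCP24) to 6.49e+07 (SCP13), with a median of 3.03e+07. Each library had between 13079 (SCP14) and 13981 (SCP32 replicate 1) genes at 1 TPM or more. Mitochondrially encoded genes held 5.97% (SCP15) to 12.9% (SCP33) of the TPM. Ribosomal protein genes held 1.42% (SCP28) to 4.67% (SCP14), with a median of 2.11%. SCP14 also had the lowest median TPM per gene, 13.1, against a median of 18.1 over the libraries.

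Libraries of different lines had a median r of 0.968 over log2(TPM + 1) and a median of 689 genes that differed by over 2-fold. The SCP32 repeats had an r of 0.985 with 108 such genes. The parental repeats had an r of 0.958 with 1228 such genes, which placed them at rank 423 from the closest among 559 pairs of different lines and the 2 pairs of repeats. SCP23 and SCP24 were the closest pair, with an r of 0.992, and their recovered reads differed by a chi-square of 1.59 per degree of freedom, against 23.8 for the SCP32 repeats and a median of 73.7 over pairs of different lines. They were kept as separate subclones, as labelled. The median SD of a gene on the log2 scale was 0.30 over the 31 subclones, 0.16 between the SCP32 repeats and 0.29 between the parental repeats. Libraries also differed by the GC content of genes: across genes, the Spearman rho of GC content with the deviation from the median library ran from -0.557 in SCP05 to 0.644 in parental replicate 1, and it was -0.219 in parental replicate 2. Genes are not independent replicates, so these values describe each library only.

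**Figure D1:**
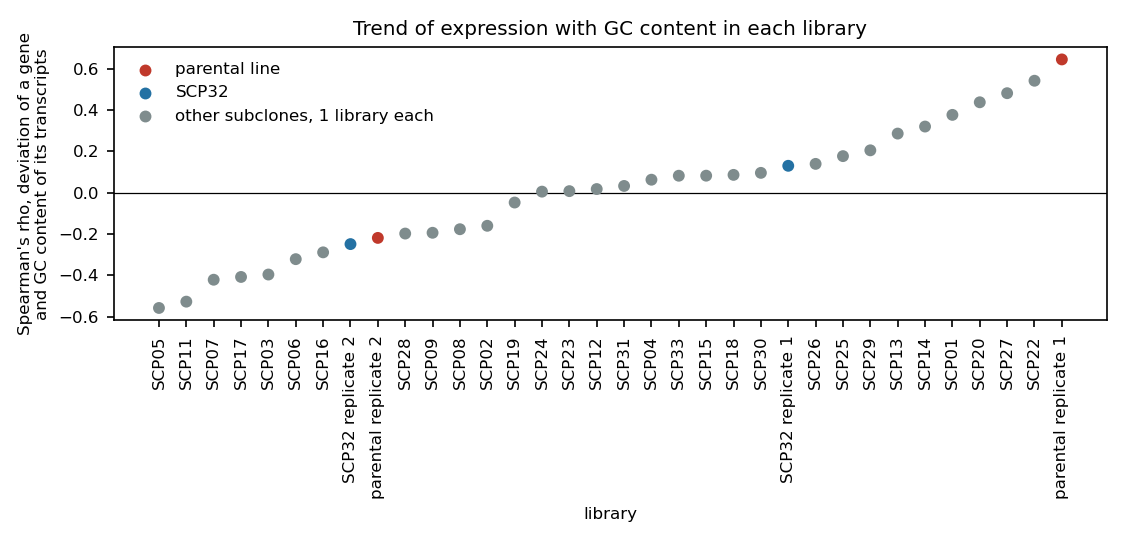
Spearman rho, across genes, of transcript GC content and the deviation of each gene from its median over 34 libraries, with libraries sorted by rho on the horizontal axis. Parental replicates (red) lie at 0.644 and -0.219, and SCP32 replicates (blue) at 0.130 and -0.249.

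The genes by which MDA-MB-468 is usually recognized were read in every library. EGFR, the growth factor receptor amplified in this line, averaged 789 ± 244 TPM (SD, n = 31 subclones) and ran from 202 in SCP14 to 1274 in SCP30; the parental libraries had 515 and 1016. RB1, the retinoblastoma tumour suppressor, averaged 0.516 ± 0.193 TPM with a highest value of 0.961. ESR1, the oestrogen receptor, averaged 1.89 ± 0.595 TPM, ERBB2 31.5 ± 6.64, BRCA1 21.8 ± 3.75, CDKN2A 56.6 ± 9.61 and MYC 87.7 ± 16.4. Markers of other cell types were few: 5 of 12 fibroblast, 2 of 15 immune, 3 of 9 endothelial and 4 of 13 neural genes were in the table. The highest levels among them were CD14 at 296 TPM in SCP12 and COL5A2 at 161 TPM in SCP09, with means of 99.8 and 80.3 TPM over the 34 libraries. These lists, like MHC class II and the metallothioneins, had fewer than 5 tested members and were not tested.

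To find the genes that set the subclones apart, the moderated F test of limma was applied. LDHB, the B subunit of lactate dehydrogenase, ran from 0 TPM in SCP11 to 235 in SCP30, with a mean of 68.4 ± 61.8 (SD, n = 31), and was at 10 TPM or more in 24 subclones. IGFBP5, a secreted binding protein of insulin-like growth factors, ran from 3.99 (SCP02) to 1952 TPM (SCP30). Of the genes of BMP signalling, BMP2, a ligand, ran from 0 (SCP17) to 60.4 TPM (SCP32), and SOSTDC1, a secreted antagonist of BMP and Wnt ligands, from 0.0734 (SCP22) to 145 (SCP30). SCGB2A2, which encodes mammaglobin A, was under 1 TPM in 18 subclones and reached 165 TPM in SCP15. FTHL17, an X-linked ferritin heavy chain-like gene, was under 0.5 TPM in 10 subclones and at 10 TPM or more in 17. PLXDC2, a plexin-domain membrane protein, was under 0.5 TPM in 16 and at 10 TPM or more in 11. The other genes that passed were C11orf53 (0 to 114 TPM), RAB34, a small GTPase (0.297 to 88.0), PBDC1 (0 to 40.4) and CSF2RA, the alpha chain of the GM-CSF receptor (0.0795 to 33.5).

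These 11 of 13762 genes passed in limma, all at the same adjusted p of 0.0453, close to the threshold of 0.05. At an unadjusted p under 0.05 there were 1191. The SD of the 11 genes on the log2 scale over the subclones ran from 1.57 (CSF2RA) to 2.27 (C11orf53). Among the fixed lists, genes that varied when adjusted over the list alone numbered 11 each for basal cytokeratins and the inflammatory NF-kB list, 9 for secreted invasion factors, 8 each for interferon response and mesenchymal genes, 7 for TGF-beta response, 6 for Wnt targets, 4 for NRF2 targets, and 3 each for stem-like and YAP target genes. The ATF4, apoptosis, cancer-testis, drug transporter, glycolysis, heat shock and MHC class I lists had 1 each, and the remaining lists had 0; adjusted over all genes, only LDHB of the glycolysis list passed. The count rose when any 1 repeat library was left out, where the residual spread came from the repeats of the other line alone. It was 4 without SCP24. With the GC correction it was 140, with a length correction 51 and with a robust variance prior 0, where 1161 genes had an unadjusted p under 0.05.

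**Figure D2:**
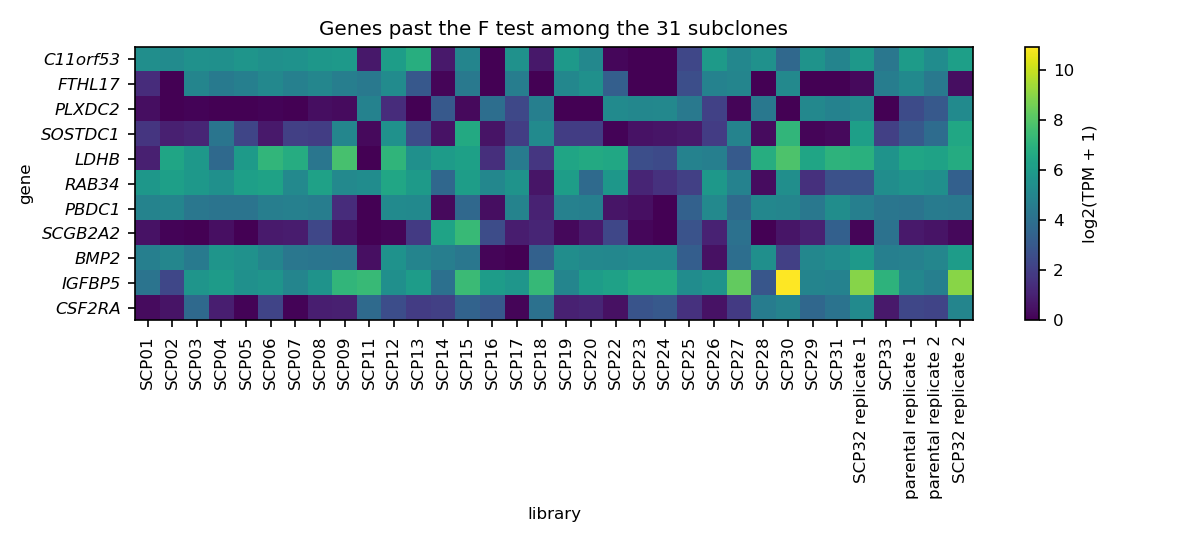
Heat map of log2(TPM + 1) of the 11 genes that passed the F test over 34 libraries. FTHL17 is under 0.5 TPM in 10 subclones and at 10 TPM or more in 17, and PLXDC2 is so in 16 and 11.

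Genes present in some lines and near 0 in others were counted next, without a test. MME, the membrane metalloendopeptidase CD10, was at 10 TPM or more in 21 of 32 lines, reached 183 TPM in SCP30 and stood at 0.0254 TPM in SCP31. CLCA2, a chloride channel accessory protein, reached 98.4 TPM in SCP28 and stood at 0.0577 in SCP30. EN1, a homeobox transcription factor, was at 10 TPM or more in 30 lines and at 0.0847 TPM in SCP31. MAGEB2, an X-linked cancer-testis antigen, was at 170.2 TPM in SCP30, the only line at 10 TPM or more, and under 0.5 TPM in 24 lines. In all, 176 genes were at 10 TPM or more in at least 1 line and under 0.5 TPM in at least 1 other, and 60 of them reached 10 TPM in a single line. LDHB, SCGB2A2, SOSTDC1 and C11orf53 were among the 10 with the highest levels. The list also held 2 short or abundant RNAs that poly-A selection should deplete, RNA28S5, a ribosomal RNA gene, at 199.99 TPM and MT-TS2, a mitochondrial tRNA gene, at 139 TPM, both highest in SCP14. Between repeat libraries the same count was 0 for SCP32 and 1 for the parental line, against a median of 5.5 over the 496 pairs of lines.

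Whether genes of a fixed list moved together from subclone to subclone was tested next, and 12 of 34 lists passed. The inflammatory NF-kB list had a mean pairwise r of 0.494: among its members, IL8, a neutrophil-attracting chemokine, averaged 11.9 ± 9.10 TPM (SD, n = 31) and ran from 0.895 (SCP14) to 37.0 (SCP32), CXCL1, a related chemokine, ran from 0 (SCP06) to 20.6 (SCP23), and LIF, a cytokine of the IL6 family, from 3.79 (SCP14) to 81.7 (SCP30). In the MHC class I list (r 0.459), HLA-B averaged 699 ± 466 TPM and ran from 96.2 (SCP28) to 2065 (SCP24), and PSMB9, an immunoproteasome subunit, from 1.46 (SCP33) to 24.5 (SCP24). Reads of the HLA genes are uncertain, since near-identical copies may share them. In the interferon response list (r 0.356), IFI44 averaged 19.9 ± 11.8 TPM and was highest in SCP05 at 44.6, and IFIT3 ran from 5.06 (SCP14) to 43.8 (SCP04). In the basal cytokeratin list (r 0.324), KRT14, a keratin of basal epithelial cells, ran from 3.14 (SCP16) to 274 TPM (SCP15), KRT6A from 3.36 (SCP04) to 125 (SCP28), and TP63, a transcription factor of basal cells, from 0.251 (SCP14) to 27.0 (SCP24). In the YAP target list (r 0.371), CTGF, a matricellular protein, averaged 30.99 ± 44.6 TPM and reached 241 in SCP30, where ANKRD1, another YAP target, reached 79.9.

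Lists of growth and metabolism also passed. In the MAPK output list (r 0.321), CCND1, the D-type cyclin of G1, averaged 129 ± 55.2 TPM and ran from 45.0 (SCP14) to 266 (SCP11), and FOSL1, an AP-1 subunit, from 3.99 (SCP14) to 22.7 (SCP23). In the mitotic list (r 0.360), MKI67, a marker of cycling cells, averaged 103 ± 29.6 TPM with its lowest value of 44.0 in SCP14. The mitochondrially encoded genes had an r of 0.628, the ribosomal proteins 0.586 and the nuclear genes of oxidative phosphorylation 0.270. In the ribosomal protein list RPS9 averaged 46.3 ± 30.3 TPM, and in the oxidative phosphorylation list COX6C averaged 114 ± 74.5. Both were highest in SCP14, at 184 and 454 TPM, where MT-ND4L was lowest, at 921 TPM. The score of the mitochondrially encoded list was lowest in SCP15, however, at -1.68 against -0.49 in SCP14. SCP14 was thus the extreme of several of these lists, and it was also the library with the highest ribosomal protein share and the fewest detected genes. Replication-dependent histones (r 0.263), whose transcripts mostly lack poly-A tails, and glycolysis (r 0.158) completed the 12.

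Adjusted p-values were 4.86e-04 for 7 of the 12 lists, whose p of 1e-04 is the smallest that 10000 random lists can give, 0.00127 for YAP targets, 0.00151 for basal cytokeratins, 0.00510 for MAPK output, 0.0340 for histones and 0.0473 for glycolysis. Glycolysis did not pass with the GC correction (adjusted p = 0.0712; 5.67e-04 to 0.0712 over its alternatives), and without SCP24 neither it (0.0567) nor the histones (0.0556; 5.23e-04 to 0.0556) passed. Of the lists that did not pass, line identity genes had an r of 0.289 and an adjusted p of 0.0594, drug transporters 0.287 (0.0788), ERBB receptors and ligands 0.247 (0.0594), cancer-testis genes 0.202 (0.0823), the ATF4 response 0.166 (0.0594), apoptosis 0.151 (0.0823), cholesterol synthesis 0.142 (0.0608) and NRF2 targets 0.132 (0.0788). Adjusted p was 0.108 for stem-like genes, 0.218 for secreted invasion factors, Wnt targets and TGF-beta response, and between 0.286 and 0.557 for the unfolded protein response, heat shock, nuclear-retained RNAs, G1/S replication, Notch, luminal, epithelial, hypoxia and mesenchymal lists.

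**Figure D3:**
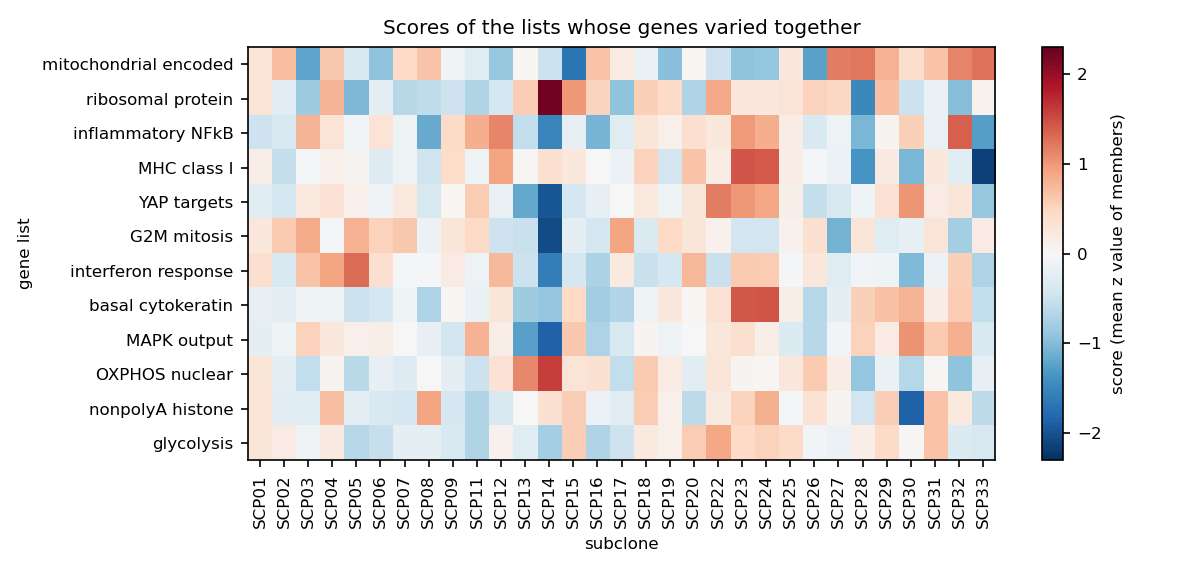
Heat map of list scores, the mean z value of the members, for the 12 lists that passed (vertical) in 31 subclones (horizontal). SCP14 has the highest ribosomal protein score, 2.22, and the lowest mitotic score, -2.07, and SCP23 and SCP24 have like values, such as 1.45 and 1.42 for MHC class I.

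To relate list scores to one another, 19 pairs fixed in advance were correlated over the 31 subclones, and 11 passed. Some of the lists had not passed the coherence test. Among these were the mesenchymal (mean pairwise r of 0.019), epithelial (0.043), G1/S (0.056) and TGF-beta lists (0.108). The score of such a list need not stand for genes that move together. EGFR level rose with the score of MAPK output genes, transcripts induced by ERK signalling, with r = 0.802 (p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 6.33e-05) and rho = 0.596 (p = 4.90e-04). SCP14 and SCP13 had the lowest MAPK scores, -1.87 and -1.24, and SCP30 one of 1.03. Without SCP13 and SCP14, the farthest from the median EGFR, r was 0.561. In these 2 libraries the median of the longest quartile of genes lay -0.37 (SCP13) and -0.68 (SCP14) from the median library. EGFR was not correlated with random lists, so a trend of whole libraries is not set apart from this relation. Mesenchymal and inflammatory scores rose together (r = 0.684, p = 1e-05, adjusted p = 6.33e-05; rho = 0.744, p = 2e-05; r = 0.650 without SCP13 and SCP33). Mesenchymal and TGF-beta scores did so with r = 0.613 (p = 1.90e-04, adjusted p = 5.16e-04; rho = 0.634, p = 1.60e-04; r = 0.575 without SCP13 and SCP30). YAP target and TGF-beta scores, with 3 shared genes left out, had r = 0.721 (p = 3.00e-05, adjusted p = 1.42e-04; rho = 0.789, p = 1e-05; r = 0.648 without SCP13 and SCP14). For this pair r was 0.480 (adjusted p = 0.0160) with a length correction and 0.436 (0.0283) with the GC and length correction, in a range of 4.75e-05 to 0.0283 over the alternatives. Interferon and inflammatory scores had r = 0.548 (p = 0.00149, adjusted p = 0.00315; rho = 0.495, p = 0.00511; r = 0.507 without SCP05 and SCP14).

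**Figure D4:**
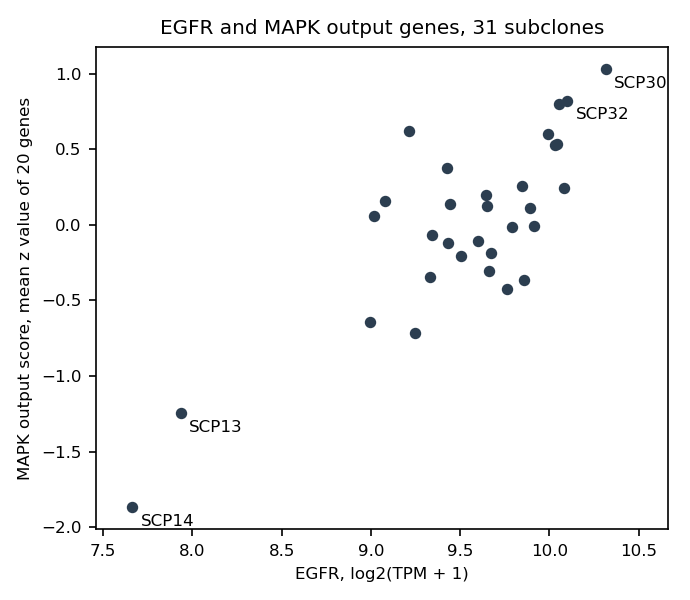
EGFR level, log2(TPM + 1), on the horizontal axis against the MAPK output score of 20 genes on the vertical axis, 1 point per subclone (n = 31). Over all points r is 0.802, and it is 0.561 without SCP13 and SCP14 at the lower left.

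Ribosomal protein and oxidative phosphorylation scores rose together (r = 0.858, p = 1e-05, adjusted p = 6.33e-05; rho = 0.849, p = 1e-05; r = 0.769 without SCP14 and SCP28). Mitotic scores rose with those of G1/S replication genes (r = 0.705, p = 9.00e-05, adjusted p = 3.42e-04; rho = 0.572, p = 9.00e-04; r = 0.407 without SCP14 and SCP27), which did not pass with the GC and length correction (r = 0.335, adjusted p = 0.0819; 2.66e-04 to 0.0819 over its alternatives) and had an r of 0.412 with the length and 0.418 with the GC correction. Mitotic scores rose with those of the ATF4 amino acid response (r = 0.492, p = 0.00515, adjusted p = 0.00978; rho = 0.461, p = 0.00960; r = 0.585 without SCP15 and SCP16), but not past the threshold with quantile normalization (adjusted p = 0.0617), a length correction (0.0835) or without SCP14 (0.0605), in a range of 0.00885 to 0.0835. They fell as ribosomal protein scores rose (r = -0.613, p = 4.30e-04, adjusted p = 0.00102; rho = -0.498, p = 0.00482; r = -0.433 without SCP14 and SCP28), a relation that ended with the GC correction (r = -0.0882, adjusted p = 0.639; 5.97e-04 to 0.639 over its alternatives) and with the GC and length correction (r = -0.263, adjusted p = 0.182).

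A pair of further relations rested on few libraries. Epithelial and basal cytokeratin scores had r = 0.662 (p = 1.10e-04, adjusted p = 3.48e-04; rho = 0.492, p = 0.00526), but r = 0.391 and an adjusted p of 0.0637 without SCP23 and SCP24, and it did not pass with the GC correction (r = 0.331, adjusted p = 0.0990; 3.26e-04 to 0.0990 over its alternatives), though it did with the GC and length correction (r = 0.429, adjusted p = 0.0283). Cholesterol synthesis and unfolded protein response scores had r = 0.468 (p = 0.00800, adjusted p = 0.0138; rho = 0.221, p = 0.231), but r = 0.154 without SCP14 and SCP28 and r = 0.273 without SCP14 alone, with an adjusted p of 0.199, the highest in a range from 0.0127. It also missed the threshold with quantile normalization (0.121) and with the GC and length correction (0.0614). Interferon and MHC class I scores had r = 0.375 with an adjusted p of 0.0555, and r = 0.467 with 0.0214 without SCP14. They also passed with quantile normalization (0.0237), the GC correction (0.0243) and both corrections (0.0211), in a range of 0.0211 to 0.174. NRF2 target and glycolysis scores had r = 0.376 (0.0555), and passed without SCP32 replicate 1 (0.0471) and with the length (0.0177), GC (r = 0.511, 0.00973) and both corrections (0.00182), in a range of 0.00182 to 0.197. The other 6 pairs did not pass: epithelial with mesenchymal (r = 0.302), cancer-testis with interferon (-0.257), hypoxia with glycolysis (0.166), ATF4 with unfolded protein response (0.0383), glycolysis with oxidative phosphorylation (0.0315) and basal with luminal (-0.0254). Of these, glycolysis with oxidative phosphorylation passed with a length correction (r = 0.544, adjusted p = 0.00426) and with the GC and length correction (r = 0.474, 0.0119), in a range of 0.00426 to 0.970 over its alternatives. ATF4 with unfolded protein response passed with the GC and length correction in the opposite direction (r = -0.408, adjusted p = 0.0370; 0.0370 to 0.950), and epithelial with mesenchymal passed with no filter (r = 0.522, adjusted p = 0.00502; 0.00502 to 0.923). Pools are not labelled, so no relation could be computed within a pool.

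SCP32, the only subclone with a repeat, was then compared with the parental line. IGFBP5 was higher by 4.10 ± 0.23 on the log2 scale (SE, n = 2 libraries each), at a mean of 504 TPM against 28.6. GDA, the enzyme guanine deaminase, rose by 3.96 ± 0.27 (37.1 against 1.41 TPM), PDZD4 was at a mean of 22.6 TPM against 0.698, and KCNS3, a potassium channel subunit, rose by 3.70 ± 0.25 and HTRA1, a secreted serine protease, by 3.56 ± 0.36. CACNG4, a calcium channel subunit, rose by 3.48 ± 0.24, TNNT1, slow skeletal troponin T, by 3.44 ± 0.32 (57.9 against 4.54 TPM), and H19, an imprinted long non-coding RNA, by 3.40 ± 0.27 (55.5 against 4.36 TPM); C4orf19 rose by 3.38 ± 0.29 and ZNF711, an X-linked zinc finger gene, by 3.35 ± 0.24. FTHL17 had the largest fall, -4.46 ± 0.33, from a mean of 28.3 TPM in the parental line to 0.285 in SCP32. GLYATL2, a glycine acyltransferase, was at 28.2 TPM against 168 (-2.53 ± 0.22), DENND2D at 6.69 against 45.1 (-2.58 ± 0.25) and RAB34 at 7.52 against 45.1 (-2.46 ± 0.29). SLC25A30, a mitochondrial carrier (-2.58 ± 0.34), ZNF512 (-2.45 ± 0.29), IFITM2, an interferon-induced membrane protein (-2.09 ± 0.28), DDX19B, an RNA helicase of mRNA export (-2.06 ± 0.27), and DDC, the aromatic amino acid decarboxylase (-1.80 ± 0.24), fell as well.

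Of 13762 genes, 106 passed in limma, 97 higher and 9 lower in SCP32, and 2078 had an unadjusted p under 0.05; adjusted p of the named genes ran from 0.00899 to 0.0385. In all 106 the libraries of the lines did not overlap, as in 49.6% of all genes, against 33.3% by chance. The median over all genes was 0.14 higher in SCP32, and 0.01 with quantile normalization, where 78 genes were higher and 14 lower. With the GC correction the median was -0.01 and the split 202 to 110. The count of 106 fell strongly with a pseudocount of 0.1 and with a filter at a mean of 5 TPM, as given below. Without 1 repeat library the count rose, and the residual spread then came from the repeats of the other line alone. The median SD was 0.16 between the SCP32 repeats and 0.29 between the parental repeats. Such counts do not rest on the same spread as the count of 106, and how far this moved them was not tested. All 106 were among the calls without either parental replicate, and 88 without SCP32 replicate 1.

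**Figure D5:**
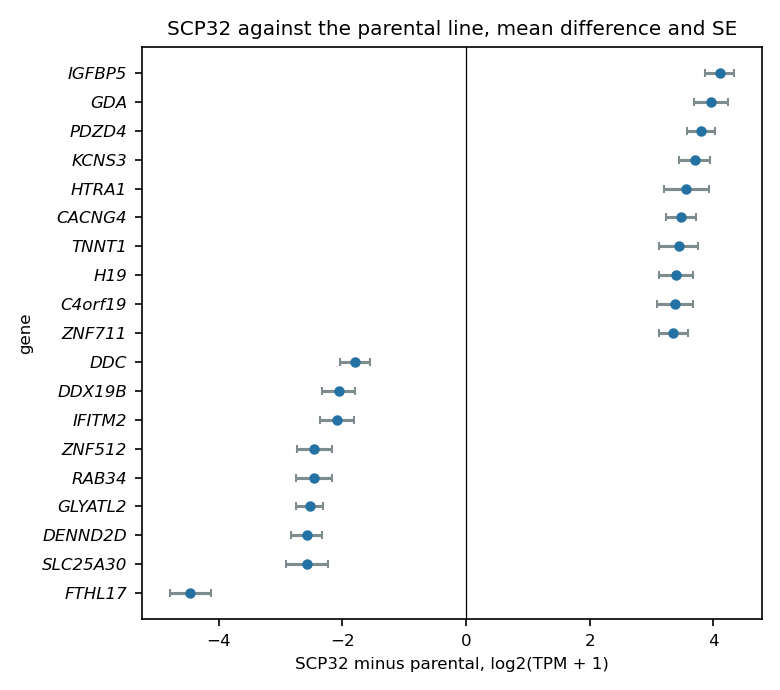
Difference of SCP32 from parental in log2(TPM + 1) for the 19 named genes, with SE (n = 2 libraries per line). IGFBP5 has the largest rise, 4.10, and FTHL17 the largest fall, -4.46.

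Of the 34 fixed lists, 13 passed with camera at the preset correlation, 8 toward higher and 5 toward lower values in SCP32. For these 13 lists the adjusted p = 0.590 to 0.607 with an estimated correlation, so 0 lists held there, and 2 of 34 had an unadjusted p under 0.05. In the inflammatory NF-kB list 18 of 19 genes were higher, with IL8 rising by 2.99 ± 0.29, CXCL1 by 2.75 ± 0.31 and TNFAIP3, a negative regulator of NF-kB, by 2.13 ± 0.30; 3 genes passed over all genes and 13 adjusted over the list alone. In the TGF-beta list 16 of 19 were higher and 4 passed (9 adjusted over the list alone), among them CTGF (3.34 ± 0.27), INHBA, an activin subunit (2.89 ± 0.24), and ID2, an inhibitor of bHLH factors (1.65 ± 0.22). In the Wnt list 13 of 14 were higher, and APCDD1, a Wnt antagonist, passed (1.63 ± 0.23; 6 adjusted over the list alone). Among the secreted invasion factors 15 of 21 were higher and 2 passed (9 adjusted over the list alone); TIMP2, a metalloproteinase inhibitor, rose by 1.67 ± 0.23. In the stem-like list 11 of 13 were higher and ALDH1A1, an aldehyde dehydrogenase, rose by 3.33 ± 0.25 (5 adjusted over the list alone). TP63 rose by 2.44 ± 0.26 in the basal cytokeratin list, where 15 of 19 were higher (9 adjusted over the list alone), and SPRY1, a feedback inhibitor of receptor tyrosine kinase signalling, by 1.90 ± 0.28 in the MAPK output list, where 16 of 20 were higher (6 adjusted over the list alone). All 13 mitochondrially encoded genes were higher, and 0 of them passed by itself, over all genes or adjusted over the list alone.

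Toward lower values in SCP32 were 39 of 40 ribosomal proteins, 26 of 30 oxidative phosphorylation genes, 22 of 25 cholesterol synthesis genes, 17 of 24 mitotic genes and 10 of 15 heat shock genes, with 0 passing by itself in each list, also when adjusted over the list alone. The parental repeats lay apart in several of these genes: RPS19 was at 527 and 141 TPM in them against 135 and 74.1 in SCP32, and NDUFA1, a subunit of complex I, at 1361 and 265 against 317 and 194. SDHB, a subunit of complex II, was at 141 and 128 TPM against 88.1 and 70.3. Camera adjusted p was 1.45e-08 for inflammatory, 3.22e-04 for TGF-beta, 4.27e-04 for Wnt, 0.00191 for invasion, 0.00223 for mitochondrial, 0.00384 for stem-like, 0.00498 for basal, 0.0133 for MAPK output, 2.25e-13 for ribosomal, 3.45e-07 for oxidative phosphorylation, 4.02e-05 for cholesterol, 0.00849 for mitotic and 0.0229 for heat shock genes. Relative to the all-gene median, the median of the list was 0.81 for inflammatory, 0.58 for TGF-beta and -0.77 for ribosomal protein genes. Fry, which asks whether the genes of a list move one way on balance, passed TGF-beta, Wnt and mesenchymal genes, each at an adjusted p of 0.0335.

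Without parental replicate 2, 6 of the 13 lists passed, namely inflammatory, TGF-beta, stem-like, ribosomal, oxidative phosphorylation and cholesterol; camera adjusted p for the others was 0.111 (Wnt) to 0.220 (mitotic). Without SCP32 replicate 1, basal (0.0591), mitotic (0.289), heat shock (0.0991), MAPK output (0.109) and mitochondrial genes (0.186) did not pass, and neither did mitochondrial genes with the GC correction (0.141). With quantile normalization mitotic (0.178) and heat shock genes (0.204) did not pass. Over the alternatives at the preset correlation the adjusted p of the inflammatory list ran up to 5.70e-05 and that of the ribosomal list up to 2.01e-05. Of the 21 lists that did not pass, mesenchymal genes (camera adjusted p = 0.0872) held NNMT, nicotinamide N-methyltransferase, which rose by 2.10 ± 0.27 (4 genes adjusted over the list alone), NRF2 targets (0.0881) held AKR1C1 and AKR1C2, both aldo-keto reductases, which rose by 2.29 ± 0.26 and 2.29 ± 0.31 (5 adjusted over the list alone), and YAP targets (0.156) held CTGF (2 adjusted over the list alone). Some of these lists passed under alternatives at the preset correlation, mesenchymal and YAP target genes toward higher and NRF2 targets and glycolysis toward lower values. Mesenchymal genes passed under 6, with an adjusted p of 0.00412 without parental replicate 1 to 0.0393 with the length correction, in a range of 0.00412 to 0.291 over these alternatives. NRF2 targets passed at a mean of at least 5 TPM (0.00290) and with the GC and length correction (0.0422), in a range of 0.00290 to 0.507. YAP targets passed without SCP32 replicate 2 (0.0372; 0.0372 to 0.375). The NRF2 list's median was -0.29 and its mean 0.02, with camera pointing down and fry up. Glycolysis had an adjusted p of 0.0519 and apoptosis 0.117, with 0 and 1 genes adjusted over the list alone. Glycolysis passed under 6 alternatives, with an adjusted p of 0.0195 at a mean of at least 5 TPM to 0.0481 with a pseudocount of 0.1, in a range of 0.0195 to 0.629. MHC class I (0.176) had 3, hypoxia (0.543) 2, interferon response (0.781) 1 and cancer-testis genes (0.646) 1. ERBB (0.149), epithelial (0.251), G1/S (0.330), ATF4 (0.418), drug transporter (0.418), line identity (0.418), luminal (0.646), unfolded protein (0.646), Notch (0.748), nuclear-retained RNA (0.781) and histone lists (0.870) had 0.

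Finally, each line was set against the 31 others with limma, 1 value per line. SCP14 stood apart most, with 1143 genes higher and 4688 lower. In this library the median gene lay -0.38 from the median library on the log2 scale, the shortest quartile of genes 0.09 and the longest -0.68, and across genes the deviation had a Spearman rho of -0.398 with gene length. The split became 1942 higher and 2289 lower with quantile normalization, 1982 and 1794 with a length correction, 2246 and 2039 with the GC correction, and 1902 and 1747 with both corrections. ROMO1, a mitochondrial membrane protein, was at 171 TPM in SCP14 against a mean of 18.8 (3.37 on the log2 scale, adjusted p = 0.00103), SCGB2A2 at 80.5 against 7.67 (5.03, 0.0107) and RNA28S5 at 199.99 against 21.6 (3.51, 0.00970). PLAU, the urokinase plasminogen activator (-3.32, 0.0242), ULBP1, a ligand of the NKG2D receptor (-2.77, 6.01e-05), and ZKSCAN8 (-2.74, 0.00309) were lower. PLAU did not pass with quantile normalization (-2.98, adjusted p = 0.0522), with a length correction (-2.89, 0.0652) or with the GC and length correction (-2.96, 0.0591), and its adjusted p was 0.0435 with the GC correction. In SCP30, with 153 genes higher and 198 lower, MAGEB2 was at 170.2 TPM against 0.782 (6.98, 1.35e-06), IGF2BP1, an oncofetal RNA-binding protein, at 42.1 against 0.322 (5.12, 2.82e-09) and IGFBP5 at 1952 against 87.2 (5.12, 0.0323). SOX11, a transcription factor of the SOX family, was at 0.119 TPM against 24.1 (-4.31, 0.00329), and the calcium-binding S100A8 (-4.26, 0.00633) and S100A7 (-4.24, 6.50e-04) were at 5.41 against 153 and 16.9 against 385 TPM.

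SCP32 had the next highest count, at rank 3, with 40 genes higher and 37 lower against the 31 others. CACNG4 (3.77, adjusted p = 0.00156), GDA (3.75, 0.0256) and H19 (3.69, 0.00156) had the largest rises, and DENND2D (-2.47, 0.0241), ZNF512 (-2.45, 0.00122) and DDX19B (-2.16, 0.00249) the largest falls, all 6 of which also changed against the parental line. The count of 77 became 202 without SCP32 replicate 1, 121 without SCP14, 184 with the GC correction and 103 with quantile normalization, where 38 were higher and 65 lower. SCP28 had 47 genes, SCP15 29, SCP24 12, SCP12 6, SCP09, SCP11, SCP13, SCP16, SCP31 and SCP33 2 each and SCP06 1. SCP23 and SCP24, the closest pair, each had the other among the 31 lines, so their counts of 0 and 12 may understate how far they stand apart. The parental line had 0 in limma, with 122 genes at an unadjusted p under 0.05, as had 17 other lines at 0; without parental replicate 2 it had 73 genes, 40 higher and 33 lower, so this count depends on that library. Lines other than SCP32 and parental have a single library, so a value apart from the rest has no repeat in those lines.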

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

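Leaving out SCP14 or SCP24, limma-voom, the rescaling of TPM, the length and GC corrections and all settings for SCP14 and SCP30 against the other lines and for runs of neighbouring genes were chosen after seeing the data. Among the alternative counts, 94 stayed within 1.5 times of the count first given and 42 moved further; these follow, and the cause was not tested except where stated. The genes varying among subclones numbered 11, and 48 with a pseudocount of 0.1, 22 with no filter, 1 with a mean of at least 5 TPM, 7 with quantile normalization, 4 without SCP24, 51 with the length, 140 with the GC and 190 with both corrections, 0 with the robust prior and 111 with limma-voom, whose calls held all 11. Without 1 repeat library they ran from 941 to 7709. SCP32 against parental gave 106, and 32, 295 and 14 under the same pseudocount, no filter and stricter filter, 312 with the GC and 481 with both corrections, and 112 to 5121 without 1 repeat library. SCP32 against the other 31 lines gave 77, and 48, 167 and 39 under those settings, 121 without SCP14, 116, 184 and 193 with the length, GC and both corrections, and 66 to 202 without 1 repeat library. SCP14 against the other lines gave 5831, and 3776 with the length and 3649 with both corrections, and SCP30 351, and 568 with both corrections. Parental against the subclones gave 0 in limma (122 at an unadjusted p under 0.05), and 0 to 73 without 1 repeat library, the highest without parental replicate 2. Lists in SCP32 against parental numbered 13, 6 to 15 without 1 repeat library and 0 with the estimated correlation (adjusted p of 0.590 or more), where 2 lists had an unadjusted p under 0.05. Lists varying together numbered 12, and 20 with the length correction; relations numbered 11, and 10 to 12 under the alternatives. Switching genes numbered 176, and 83 with an upper threshold of 20 TPM and 102 with a lower threshold of 0.1 TPM, both stricter by construction. Windows of shifted neighbouring genes numbered 1009, and 605 with the GC and 623 with both corrections. Of the 19 named genes of SCP32 against parental, 317 values under alternatives kept direction and call, and 19, all in DDC, IFITM2, DDX19B, SLC25A30, RAB34, HTRA1 or ZNF512, kept the direction but not the call. With the replicate number as a replicate block, 5454 genes varied among subclones and 3248 differed between SCP32 and parental, and 14 lists passed. Across genes, replicate 2 minus 1 had r = 0.591 between SCP32 and parental, and r = 0.551 after the length correction. The rho with GC content fell from replicate 1 to 2 in both lines, from 0.130 to -0.249 in SCP32 and from 0.644 to -0.219 in parental. The repeats of the 2 lines thus moved alike, which the main fit leaves in the residual spread. The labels do not say what the shared number stands for, and 2 pairs cannot tell. Runs of neighbouring genes with an annotation of the build of the table, and the 4 alternatives to them, were not run, because such an annotation was not used here. Depth limits low genes most in SCP24, with 8.64e+06 reads.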

Other observations

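The study of neighbouring genes, its corrections for length and GC content, and the tests of counting noise, of 1 library under 2 names, of gene length in the runs, of GC content in large shifts and the count of X-linked genes were chosen only after the result was seen.

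Several genes outside the lists that passed varied widely over the 31 subclones, given here as values without a call. Among secreted factors, TIMP3, an inhibitor of metalloproteinases, averaged 33.1 ± 77.9 TPM (SD, n = 31) and reached 441 in SCP30, MMP7, matrilysin, ran from 0.388 (SCP29) to 71.3 (SCP15), and PLAU from 0.635 (SCP16) to 69.1 (SCP27). KIT, a receptor tyrosine kinase of luminal progenitors, was at 0 TPM in SCP24 and 81.2 in SCP15, where KRT14 and SCGB2A2 were also highest and VIM, an intermediate filament of mesenchymal cells, reached 30.9 against a mean of 4.79 ± 5.43. ALDH1A1 ran from 6.74 TPM in SCP30 to 188 in SCP32, and AKR1C2 from 0.881 in SCP02 to 107.5 in SCP24. CA9, a carbonic anhydrase induced by hypoxia, ran from 8.56 (SCP27) to 109 (SCP28), and CRYAB, a small heat shock protein, from 5.61 (SCP28) to 127 (SCP11).

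Neighbouring genes moved together in single lines. In windows of 50 genes, taken in the gene order of GRCh38, 1009 of 11104 pairs of line and window lay apart from the other lines, 395 above and 614 below, where chance would give a call in 1.6 lines. The window from AIG1 to ACAT2 on chromosome 6 had a median shift of -1.23 on the log2 scale in SCP28, in a run that began at CCNC, and was lower in SCP31, SCP32, SCP08 and SCP29 as well (-0.44 to -0.26). The window from DERL1 to EXOSC4 on chromosome 8 was higher in SCP33, SCP27, SCP14 and SCP15, by 0.88, 0.82, 0.75 and 0.53, and lower in SCP06 (-0.21). That from AQP3 to SHB on chromosome 9 was lower in SCP08 (-0.84), SCP31 (-0.65), SCP01 (-0.20) and SCP07 (-0.18), and higher in SCP30, SCP29 and the parental line (0.15 to 0.28). In SCP32 the window from DYNC1LI2 to EXOSC6 on chromosome 16 was lower (-0.81). The window from UBOX5 to RIN2 on chromosome 20, in a run where BMP2 lies, was lower in SCP30 (-0.80), SCP27, SCP11 and SCP15 (-0.46 to -0.31), and that from ATAD3A to NMNAT1 on chromosome 1 in SCP30 (-0.74), SCP32 (-0.42) and SCP15 (-0.30). Of the 19 genes named for SCP32 against the parental line, 7 lay in runs of SCP32. DDX19B, GLYATL2, ZNF512, IGFBP5, HTRA1 and TNNT1 changed in the direction of their run, and KCNS3 in the opposite one. The share of all genes in runs of SCP32 was not computed, so 7 of 19 cannot be read as an excess. Each gene changed by more than its run, such as DDX19B by -2.06 in a run of -0.81 and IGFBP5 by 4.10 in a run of 0.51. Runs are measured from the median of the lines, and these changes from the parental line. Other windows recurred as well. The genes from ANKZF1 to MLPH on chromosome 2 were higher in SCP28, SCP29, SCP31 and SCP32 by 0.47 to 0.51. Those from FHDC1 to TLR3 on chromosome 4 were higher in 8 subclones, SCP23 and SCP24 among them, by 0.31 to 0.64 and lower in SCP33, SCP20 and SCP02 by -0.27 to -0.12. Those from MARS2 to ATIC on chromosome 2 were lower in 7 subclones by -0.67 to -0.31 and higher in SCP05 and SCP07 by 0.31 and 0.17. Those from RHBDF2 to ANAPC11 on chromosome 17 were lower in 6 of the 8 subclones higher from FHDC1 to TLR3, by -0.54 to -0.24.

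For these runs, gene length, scaling between libraries and the preparation of a single library were weighed against dosage of whole segments. Length and scaling were excluded as the whole cause, as 83.4% and 88.8% of the calls stayed after the length correction and quantile normalization. Against a single preparation, the SCP32 repeats had an r of 0.706 over windows, at rank 25 of the pairs of libraries, which met the bound set before, and 0.921 and 0.938, both at rank 2, after the GC and after both corrections; it stays open because that bound named 1 pair, and the parental repeats had an r of -0.497, at rank 503, which rose to 0.129 (rank 122) and 0.276 (rank 60) with those corrections. GC content stays open for the small shifts, of which it ended many, since 50.1% of all calls stayed after its correction. Of the 45 calls of at least 0.5, 77.8% stayed. Outside SCP14 all such calls held under every correction, so GC content is excluded as their whole cause. In SCP14 only the windows from DERL1 to EXOSC4 and from MARS2 to ATIC held throughout. Its largest shift, 0.86 from IVL to HCN3 on chromosome 1, did not hold, so GC content stays open for the other large shifts of SCP14. Genes of lower level that took no part in the windows shifted the same way in 39 of 40 windows with a shift of at least 0.5, or 97.5%. They did so in 29 of 29 after the GC correction and in 22 of 23 after both corrections. Their median shift relative to that of the window was 0.72, 0.70 and 0.60. Neighbouring windows share genes, so they are not separate checks, and the uncorrected windows cannot tell dosage from GC content. Gained or lost copies of segments are a candidate explanation for the large runs, but copy number was not measured here.

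SCP23 and SCP24 were closer to one another than any other pair. Their reads had a chi-square of 1.59 per degree of freedom, against 16.5 for the next pair of lines and 23.8 for the SCP32 repeats. This is what 1 library or RNA sample under 2 names might give. Whether SCP23 and SCP24 differ by more than sampling noise cannot be told from this value, because the recovered reads may not be independent. Their window profiles had an r of 0.959, which closely related subclones would give as well, so the data leave both open. Between them, 3 genes were at 10 TPM or more in one and under 0.5 TPM in the other. These were MT-TS2, MT-TC and SNORD38A, all at 0 TPM in SCP24, the shallowest library. The genes had few reads in every library, so a true difference cannot be told from low depth here. Counting SCP23 and SCP24 once left 4 of the 11 genes that varied among the subclones.

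The parental libraries differed by more than the median pair of libraries of different lines, with an r of 0.958 against 0.968. Counting noise is excluded, with a chi-square of 186 per degree of freedom, and so is gene length as the whole cause, as the pair stayed at rank 389 from rank 423 after its correction. GC content stays open, since the pair moved to rank 249 after that correction, short of the rank among the closest pairs that was set as the bound, and no biological explanation was tested. A mislabelled library stays open too: over windows the pair had an r of -0.497 and replicate 1 an r of 0.868 with SCP20, which met the bound set before, and after the GC correction replicate 2 had an r of 0.484 with SCP05 against 0.129 for the pair, which met it again. These profiles follow GC content, however, and after the GC and length correction the bound was no longer met: the pair had an r of 0.276, higher than any other for replicate 1, and SCP05 was closest to replicate 2 with 0.418; the weight given to these values was decided after they were seen.

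As a hypothesis, X-linked genes may switch between on and off more often than autosomal ones. Among genes at 10 TPM or more in at least 1 line, 16 of 334 genes placed on chromosome X (4.79%) were under 0.5 TPM in another line. FTHL17, PBDC1, MAGEB2, MAGED1 and CSF2RA were among them. Of autosomal genes 128 of 9292 (1.38%) were, an odds ratio of 3.602, or 3.45 without the cancer-testis list. The placement does not set apart genes shared with chromosome Y, and genes without a placement, such as KAL1, took no part. The hypothesis came from these same genes, so the ratio describes them and does not test it, and it stays open. A further hypothesis was that EGFR level follows the dosage of its segment. The score of the 5 tested genes on each side had r = 0.550 with EGFR over the 31 subclones (permutation p = 0.00156; rho = 0.467, p = 0.00847; r = 0.370 without SCP13 and SCP14), which met the bound set before, but r was 0.0911 after the GC and 0.132 after the length correction. EGFR-AS1, which overlaps EGFR, is among these neighbours, so the relation may come from shared reads or from GC content, and the hypothesis stays open; the weight given to the corrected values was decided after they were seen.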
